A study of Setaria viridis and Sorghum bicolor with 8 samples.

How the data were processed

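PARE (parallel analysis of RNA ends) libraries were made from total RNA of 2 grasses, *Sorghum bicolor* and *Setaria viridis*. The method captures the 5′ ends of uncapped, polyadenylated RNA fragments and turns each into a short sequence tag, so that a fragment left by a small RNA-guided cut gives a tag that starts at the cut. Each species had 4 libraries, and each tissue or stage was represented by 1 library, so that no difference between tissues or stages has a replicate check and no p-value is given for one. The samples were a leaf library and 3 reproductive libraries of each species. The Setaria reproductive libraries were a panicle at stage 3, spikelets at stage 3 and spikelets at stage 4. The sorghum reproductive libraries were spikelets with anthers under 0.5 mm, spikelets with anthers of 0.5 to 1.2 mm, and spikelets labelled as over 1.2 mm, a length whose object the label does not name.

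Per the labels' protocols, RNA was extracted with Trizol, libraries followed a modified PARE protocol with small RNA index adapters, and sequencing used an Illumina HiSeq 2500. The deposited files list each distinct tag with its count, and these counts are whole numbers that had not been scaled to library size. Every deposited tag was 18 to 20 nt long. Trimming tools, read filters, any aligner and any genome build are not given in the sources used here. No genome sequence was used here, so tags were not placed on chromosomes or genes, and the planned comparisons of genes and of positions around stop codons were not run. The lists of photosynthesis, tapetum and meiosis genes prepared for that step were therefore not used, and no cell types were called.

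Tags were read against 29 small RNA families that are widely conserved in plants or known from grasses. Their sequences were written from general knowledge of these families and not taken from a database, so variants of these species can be missing, and a family that was not called can still have been active. A plant small RNA guides cutting between the bases that pair with its positions 10 and 11. Where a target pairs fully with small RNA positions 1 to 10, the tag's first 10 nt are the reverse complement of these positions. This 10-nt word was searched at the start of every tag, so sites that pair imperfectly there were missed unless a listed variant matched. Families with sequence variants had several words, up to 8 for miR2118. The background was the mean count of the same words when they started 1 to 10 nt inside a tag of the same library, which keeps base composition fixed. The ratio of the start count to this background used a pseudocount of 0.5 and was placed among 10000 random word lists matched on background. A family was called in a library at 10 or more counts and a ratio above the 99th percentile of the random lists. The same words read backwards served as control lists.

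Levels are given in TPM, here tags per 1000000 counts of the library's deposited total. Their 95% intervals are exact Poisson intervals, and those of log2 ratios are exact conditional binomial intervals. The libraries had no molecular identifiers, so all intervals, and limits from a count of 0 (3 counts of the library total), cover counting error only. Where a ratio was taken over a family's own background, the interval held that background fixed and left out its error. A direction against leaf was given to a family only where all 3 reproductive libraries lay on 1 side of leaf with intervals that excluded 0, and the smallest of the 3 log2 ratios was reported. Identical tags in pairs of libraries were counted after random thinning to the smallest total, 21544530 counts. Total counts per library ran from 21544530 to 50059249, so that a count of 0 allows a level of up to 0.0599 to 0.139 TPM.

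The rules, lists and most alternatives were fixed before the data were examined. The text names every family by class with values for those called in at least 1 library, the most abundant tag of each called family, and for each species 10 other words. These are words that differ from every listed word by more than 2 bases and have the largest ratio to background in any library. They needed at least 5 TPM and at least 5 tags that differ from each other by 3 or more bases. Tags named outside this rule are said to have been chosen after their values were seen. Alternatives were a 9-nt word, up to 1 mismatch outside the first 2 tag positions, tags with at least 2 counts, distinct tags each counted a single time, background offsets from 3, removal of each family's most abundant tag, the 95th percentile, a minimum of 30 counts, a pseudocount of 1, scaling without the 100 most abundant tags of each library, and the ratio to the family's own background. The median of the background offsets was added after the data had been seen.

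The call was tested on simulated data in the 8 libraries. All simulated words had a mean background of at least 10 counts, so families with a lower background are not covered. Words raised 20-fold over background were called in 100% of the 100 simulated words of every library. Words raised 5-fold were called in a median of 43% of 100 words per library, from 7% to 84% between libraries, so that a family with a small excess can be called in one library and missed in another. Of 200 unchanged words per library, a median of 1.5% were called. Their ratios were drawn from words of like background, so the threshold largely sets this share. Simulated log2 ratios for the Setaria panicle and leaf totals fell inside their intervals in 95.4% to 96.2% of 2000 draws at each of 6 settings. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.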

Results

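The series holds 8 PARE libraries, 4 from *Setaria viridis*, a small wild relative of foxtail millet, and 4 from *Sorghum bicolor*, a cereal crop. Both are grasses, and in each species a leaf library stood beside 3 libraries of reproductive tissue. The stages were taken along panicle and spikelet development in Setaria and along anther development in sorghum, as far as the labels describe them. The Setaria totals were 41111973 counts for leaf, 39361154 for the stage 3 panicle, 33782804 for stage 3 spikelets and 31938612 for stage 4 spikelets. The sorghum totals were 50059249 counts for leaf, 29992644 for spikelets with anthers under 0.5 mm, 21544530 for those with anthers of 0.5 to 1.2 mm and 24121530 for those over 1.2 mm. Each library held between 4173266 and 6203196 distinct tags. The 100 most abundant tags took 12.7% of the counts of Setaria leaf and 19.9% of those of sorghum leaf, against 1.78% to 3.5% in the 6 reproductive libraries. The tag TACCTGGTTGATCCTGCCAG, which has the sequence with which plant 18S ribosomal RNA is known to begin, reached 23741 TPM in Setaria leaf and 43088 TPM in sorghum leaf. Tags with an unread base made up 0.859% to 0.897% of the counts of the 3 sorghum spikelet libraries and 0.00777% to 0.00825% of those of the other 5.

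Which small RNA families left tags at their predicted cutting position was asked of each library by itself. miR160 stood out in all 8 libraries. This family is known to direct the cutting of transcripts for auxin response factors, which switch auxin-responsive genes. Its level ran from 128 TPM in Setaria stage 3 spikelets (95% interval 124 to 132) to 1913 TPM in sorghum leaf (1901 to 1925), and its smallest ratio to background in any library was 316. miR156 and miR529, both known to target SPL transcription factors that time phase change and shape the inflorescence, were each called in 5 libraries. miR2118, which triggers reproductive phased small RNAs of 21 nt in grasses, was called in 4 libraries, and miR2275, which triggers those of 24 nt, in 1.

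In the auxin group, 2 of 5 families were called. The sorghum miR160 tags were dominated by GAGCCAGGCATGCGCAATTC, which made up 92.0% to 95.2% of the family's counts in all 4 libraries. In Setaria the leading miR160 tag was GAGCCAGGCATGCGCAATTT in leaf, at 45.6% of the family, and GAGCCAGGCATGCTCAATTC in the 3 reproductive libraries, at 67.3% to 73.0%. The trans-acting small RNA tasiARF, which targets further auxin response factors, was called in the 3 reproductive Setaria libraries at 15.2 to 23.2 TPM and in sorghum spikelets with anthers under 0.5 mm at 12.1 TPM. Its leading tag in Setaria was AGGTCAAGAAGTGTTTCGTC, with 487 counts in the panicle, and AGGTCAAGAACTCGTACAAG led in that sorghum library with 80 counts. miR167, miR390 and miR393 were not called in any library with the words used, although miR393 was called in 3 libraries with distinct tags and miR390 in 1 with a 9-nt word and in 1 with 1 mismatch.

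In the development group, 5 of 13 families were called. miR156 was called in the 4 Setaria libraries at 81.7 to 390 TPM, led in each by TCTTCTGTCATGCAGCTAAG, and in sorghum leaf at 21.4 TPM, led by TCTTCTGTCAGTTGGCGCTT. miR529 was called in the Setaria panicle at 40.01 TPM, in stage 4 spikelets at 12.5 TPM and in the 3 sorghum spikelet libraries at 55.3 to 60.01 TPM. TCTCTCTTCTGTCAACTCAG led the miR529 tags in the panicle and in the 3 sorghum spikelet libraries, where it held 75.4% to 83.4% of the family. miR164, whose known targets are NAC transcription factors of organ boundaries, was called in the 4 Setaria libraries, with 17.3 TPM in stage 3 spikelets and 181 TPM (176 to 185) in stage 4 spikelets. Its leading tag was TGCTTCTCCAGCTTCAACAA, or the same tag 1 base shorter in the spikelet libraries. miR319, which targets growth-regulating TCP factors, was called in the 3 reproductive Setaria libraries at 6.30 to 14.7 TPM and led by TTCAGTCCAATTCGCAGCCG. miR171, which targets GRAS factors of the meristem, was called in sorghum leaf at 10.05 TPM, in spikelets with anthers under 0.5 mm at 12.1 TPM and in those with anthers of 0.5 to 1.2 mm at 7.89 TPM. Its leading tag there was GGCTCAATCACCAGCTTCCC, with 323 counts at under 0.5 mm. miR159, miR166, miR169, miR172, miR394, miR396, miR444 and miR535 were not called in any library with the words used, which leaves sequence variants and imperfectly paired sites open.

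In the group of nutrient and copper families, 3 of 7 were called, each in 1 library. miR408, known to target copper proteins, reached 26.6 TPM in the Setaria panicle, and GGCAGTGCAGGACTATTCTT made up 95.7% of it. miR395, known to target sulfate assimilation, reached 1.75 TPM in Setaria stage 3 spikelets with 59 counts, of which 57 were AACACTTCACGTCATTACTG. miR528, which also targets copper proteins, reached 1.92 TPM in sorghum leaf with 96 counts, led by GCCCCTTCCAAAATCCCGAG with 30. miR397, miR398, miR399 and miR827 were not called. Neither of the small RNA machinery families, miR162 and miR168, was called in any library, and variants of their words were not searched beyond 1 mismatch.

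**Figure D1:**
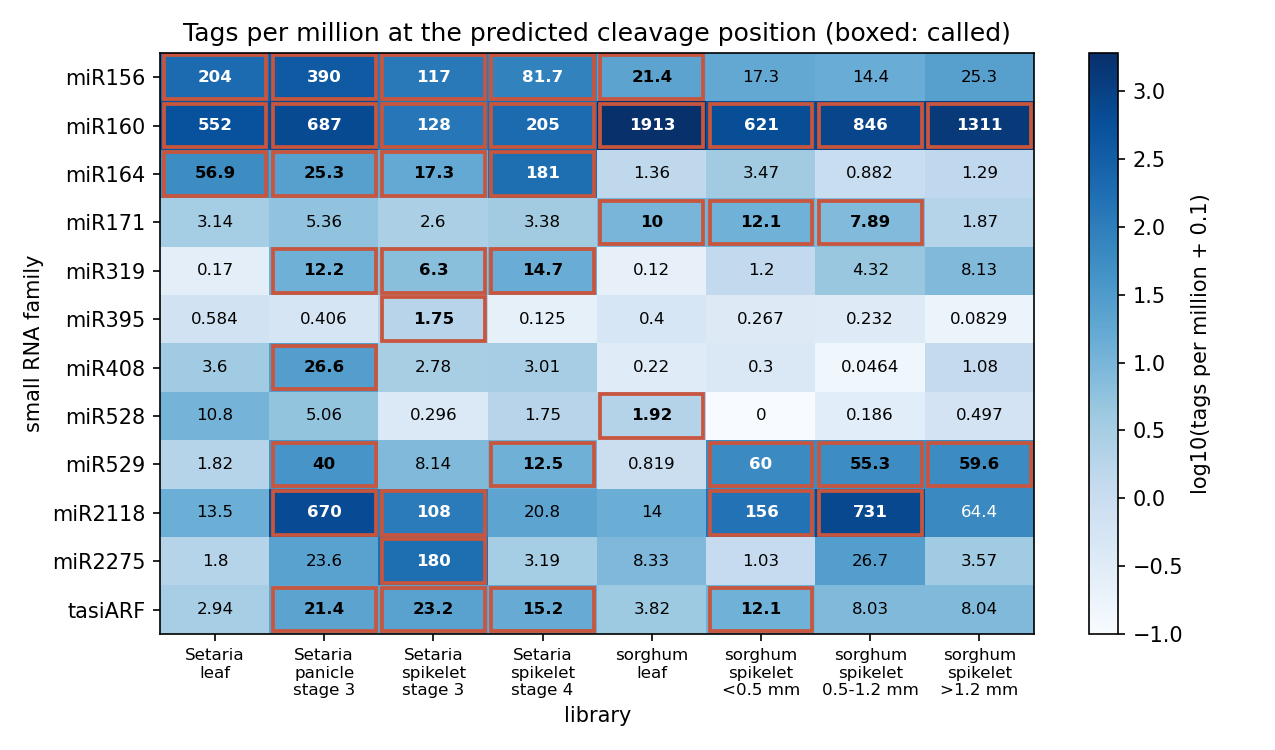
Tags per 1000000 counts at the predicted cutting position, for the 12 families called in at least 1 library (vertical axis) and the 8 libraries (horizontal axis), with a log10 colour scale and called cells boxed. miR160 is boxed in all 8 columns, and miR2118 is highest in the Setaria panicle (670 TPM) and in sorghum spikelets with anthers of 0.5 to 1.2 mm (731 TPM).

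In total 40 of 232 combinations of family and library were called, against 3 of 232 for the words read backwards and 2.32 by the threshold alone. The backward words called were those of miR171 in Setaria leaf and stage 3 spikelets and of miR396 in stage 4 spikelets. A 9-nt word that leaves out the base opposite small RNA position 1 added miR166 in 6 libraries and miR169 in 7, and lost 3 of the 4 tasiARF calls and 1 call each of miR156, miR171, miR319, miR395 and miR528. Distinct tags lost 2 of 3 calls each of miR319 and miR171, 2 of 4 of tasiARF, the only calls of miR395 and miR408, and miR529 at over 1.2 mm. With 1 mismatch allowed, no call of tasiARF, miR319, miR171, miR395 or miR408 was kept, and 4 of the 5 miR529 calls, 2 of the 4 miR164 calls and 1 miR156 call were lost. miR395 and the sorghum leaf call of miR528 were also lost when the background started at offset 3.

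Leaf was compared with the reproductive tissues within each species. In Setaria, 5 of the 10 called families were higher in all 3 reproductive libraries than in leaf, none was lower in all 3, and 5 were mixed. miR319 tags rested on 7 counts in leaf, 0.170 TPM (0.0685 to 0.351), and were higher by 5.11 (4.14 to 6.54) or more on the log2 scale in each reproductive library, a ratio that came to 0.78 with distinct tags, 0.96 with 1 mismatch, 1.67 with a 9-nt word and 3.90 without the most abundant tag. tasiARF was at 2.94 TPM in leaf and higher by 2.37 (2.08 to 2.67) or more, a ratio that came to 0.56 with distinct tags and −0.52 with 1 mismatch. miR529 was at 1.82 TPM in leaf and higher by 2.15 (1.78 to 2.55) or more, but its ratio came to 0.66 with a 9-nt word, 0.84 with distinct tags and 0.06 with 1 mismatch, where it no longer differed from leaf in all 3 libraries. miR2118 and miR2275 were higher in stage 4 spikelets than in leaf by 0.62 (0.46 to 0.79) and 0.82 (0.38 to 1.28), although neither was called in those 2 libraries. The miR2118 ratio came to 0.22 over its own background, and the miR2275 ratio to 0.03 with distinct tags, 0.00 with a 9-nt word and −3.51 with 1 mismatch. The miR2275 direction was lost with distinct tags and with a 9-nt word. With 1 mismatch it was reversed, miR2275 being lower than leaf in all 3 reproductive libraries. miR2118 had ratios to background of 1.10 and 0.948 in stage 4 spikelets and leaf, and miR2275 had 0.688 and 0.278.

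The mixed Setaria families had their extremes in different tissues. miR164 was 1.67 (1.60 to 1.74) higher on the log2 scale in stage 4 spikelets than in leaf, while its ratio was −1.17 in the panicle and −1.71 in stage 3 spikelets. miR156 and miR160 were higher in the panicle than in leaf by 0.94 (0.90 to 0.98) and 0.32 (0.29 to 0.34), and had ratios of −0.80 and −2.11 in stage 3 spikelets and of −1.32 and −1.43 in stage 4 spikelets. Over their own background, miR156 and miR160 were lower than leaf in all 3 reproductive libraries. The panicle's miR156 background, however, included its leading miR529 tag, which holds the miR156 word inside it. With the median of the offsets as background, a choice made after the data were seen, the miR156 ratio to background was 64.6 in the panicle. It was 47.4 in leaf, 22.0 in stage 3 spikelets and 10.2 in stage 4 spikelets, so the panicle then lay above leaf. miR408 was 2.88 (2.63 to 3.14) higher in the panicle than in leaf and did not differ beyond counting error in either spikelet library. miR395 was 1.56 (0.87 to 2.33) higher in stage 3 spikelets than in leaf. Its ratio was −2.08 (−4.21 to −0.68) in stage 4 spikelets, from 4 counts, and it did not differ beyond counting error in the panicle. Counted as distinct tags, none of the 5 Setaria directions held, and without the 100 most abundant tags all 5 did, with a shift of −0.15 to −0.17 in every ratio to leaf.

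In sorghum, 3 of the 7 called families were higher in all 3 spikelet libraries than in leaf, 2 were lower and 2 were mixed. miR529 was at 0.819 TPM in leaf (0.588 to 1.11), where it was not called, and at 55.3 to 60.01 TPM in the spikelets, a smallest log2 ratio of 6.06 (5.63 to 6.56) that came to 1.66 with distinct tags and 2.56 with 1 mismatch. miR2118 was higher by 2.20 (2.07 to 2.33) or more, or by 0.79 with distinct tags and 1.17 over its own background. tasiARF was higher by 1.07 (0.77 to 1.38) or more in TPM, but over its own background its smallest ratio was −0.64. miR160 was lower in the spikelets, with ratios of −1.62 at under 0.5 mm, −1.18 at 0.5 to 1.2 mm and −0.55 (−0.56 to −0.53) at over 1.2 mm. The smallest of its 3 ratios ran over the alternatives from −1.73 over its own background to −0.15 with distinct tags. miR528 had 96 counts in leaf and 0, 4 and 12 in the spikelets in order of anther length, with a smallest ratio of −1.90 (−2.95 to −1.08), a direction that was mixed over its own background. The 0 counts at under 0.5 mm allow up to 3 counts of that library's total. miR171 was mixed, at 0.27 (0.07 to 0.47) above leaf at under 0.5 mm and with a ratio of −2.41 at over 1.2 mm. miR156 was mixed too, with ratios to leaf between −0.57 and 0.24, but over its own background it was lower than leaf in all 3 spikelet libraries. That background included the leading miR529 tag of the spikelets, which holds the miR156 word inside it.

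The sorghum leaf library also differed from the 3 spikelet libraries in its share of counts with an unread base, so that batch and tissue cannot be told apart in this comparison. Leaving out the 100 most abundant tags shifted every sorghum ratio to leaf by −0.27 to −0.29 and kept the 5 directions. Counted as distinct tags, 2 of the 5 were kept, those of miR529 and miR2118, and those of miR160, miR528 and tasiARF were not. For miR528 the smallest ratio was still −1.55, with an interval that reached 0.14.

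Between the species, 5 families were called in both, miR156, miR160, miR529, miR2118 and tasiARF. miR529, miR2118 and tasiARF were higher than leaf in the reproductive libraries of both species by TPM, and no family had opposite directions in the 2 species. miR164, miR319, miR395, miR408 and miR2275 were called in Setaria libraries alone, and miR171 and miR528 in sorghum libraries alone. Those differences in calls were not tested. miR171 tags, for example, stood at 2.60 to 5.36 TPM in Setaria and reached the percentile 98.9 of the random lists in the panicle.

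The reproductive libraries of each species were compared for the triggers of phased small RNAs. In Setaria the panicle and the first spikelet library carry the same stage number, 3, and differ in the organ named. The labels do not say whether panicle and spikelet stages are numbered on 1 scale, so these 2 can differ in stage as well. In sorghum, miR2118 tags were at 156 TPM (151 to 160) with anthers under 0.5 mm, 731 TPM (720 to 742) with anthers of 0.5 to 1.2 mm and 64.4 TPM (61.2 to 67.7) at over 1.2 mm, against 14.02 TPM in leaf. The middle stage exceeded the early one by 2.23 (2.18 to 2.28) on the log2 scale and the late one by 3.5 (3.43 to 3.58), the smaller of which came to 1.33 (1.12 to 1.54) with distinct tags. In Setaria, miR2118 tags were at 670 TPM (662 to 679) in the stage 3 panicle, 108 TPM (104 to 111) in stage 3 spikelets and 20.8 TPM (19.2 to 22.4) in stage 4 spikelets, against 13.5 TPM in leaf. The panicle exceeded stage 3 spikelets by 2.64 (2.59 to 2.69) and stage 4 spikelets by 5.01 (4.90 to 5.12), and with distinct tags the smaller ratio was 1.72 (1.52 to 1.94). At over 1.2 mm, sorghum miR2118 lay at percentile 98.8 of the random lists and was not called. It was called there with a 9-nt word, 1 mismatch or distinct tags, without the most abundant tag, and at the 95th percentile.

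miR2118 tags were spread over many sequences. GCATCAAGAAATGTGATGTT led in the Setaria panicle with 11.3% of the family, GCATTAGGAACTCAATTATG in Setaria stage 3 spikelets with 19.02%, and GCATCAGGAAAGAAGCTACT in the sorghum 0.5 to 1.2 mm library with 10.5%. In sorghum leaf and in the other spikelet libraries the leading miR2118 tag was GCATCAAGAAGGACGATGAC, with 584 counts at under 0.5 mm and 644 at over 1.2 mm, where it made up 41.5% of the family. Among full-length miR2118 tags with at least 5 counts, sorghum had 83, 121 and 36 in order of anther length, and 73 of the 83 from the earliest library were also seen at 0.5 to 1.2 mm. In Setaria there were 196 such tags in the panicle, 67 in stage 3 spikelets and 18 in stage 4 spikelets, and 39 of the 196 panicle tags were also seen in stage 3 spikelets. Only 1 tag with at least 5 counts was shared between the Setaria panicle and the sorghum 0.5 to 1.2 mm library.

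miR2275 tags peaked in other Setaria tissue. They were at 180 TPM (175 to 184) in stage 3 spikelets, 23.6 TPM (22.1 to 25.1) in the panicle and 3.19 TPM (2.60 to 3.88) in stage 4 spikelets, against 1.8 TPM in leaf. Stage 3 spikelets exceeded the panicle by 2.93 (2.83 to 3.03) and stage 4 spikelets by 5.81 (5.53 to 6.11), the smaller of which came to 1.16 (0.76 to 1.58) with distinct tags and 1.52 (1.49 to 1.55) with 1 mismatch. With 1 mismatch, however, miR2275 was also called in Setaria leaf and was higher there than in each reproductive library. GAAAAACAAATCAATGTTTG held 40.2% of the miR2275 counts in stage 3 spikelets. In the panicle miR2275 lay at percentile 98.3 of the random lists and was not called. In sorghum miR2275 had 575 counts, 26.7 TPM (24.6 to 29.0), with anthers of 0.5 to 1.2 mm, at percentile 92.3, and 1.03 and 3.57 TPM with shorter anthers and at over 1.2 mm. After thinning to the smallest total, sorghum leaf had 179 counts, against 18, 575 and 72 in the spikelets in order of anther length. Leaf thus lay above the earliest and the latest spikelet library. The level pools unlike words, however. In sorghum leaf the word GAAAAACAAA made up 86.1% of the miR2275 counts, against 3.3% at 0.5 to 1.2 mm. In that spikelet library GGAAACCAAA and GGAAACTAAA made up 46.1% and 48.2%. The smallest log2 ratio of that middle stage to the other spikelet libraries was 2.90 (2.58 to 3.25), and it came to 0.96 (0.15 to 1.85) with distinct tags and −0.46 with 1 mismatch. Leading tags were GGAAACTAAAATACCATGTT in the sorghum middle stage, with 266 counts, and GGAAACTGAAAATGGGCACT in the Setaria panicle, with 248.

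**Figure D2:**
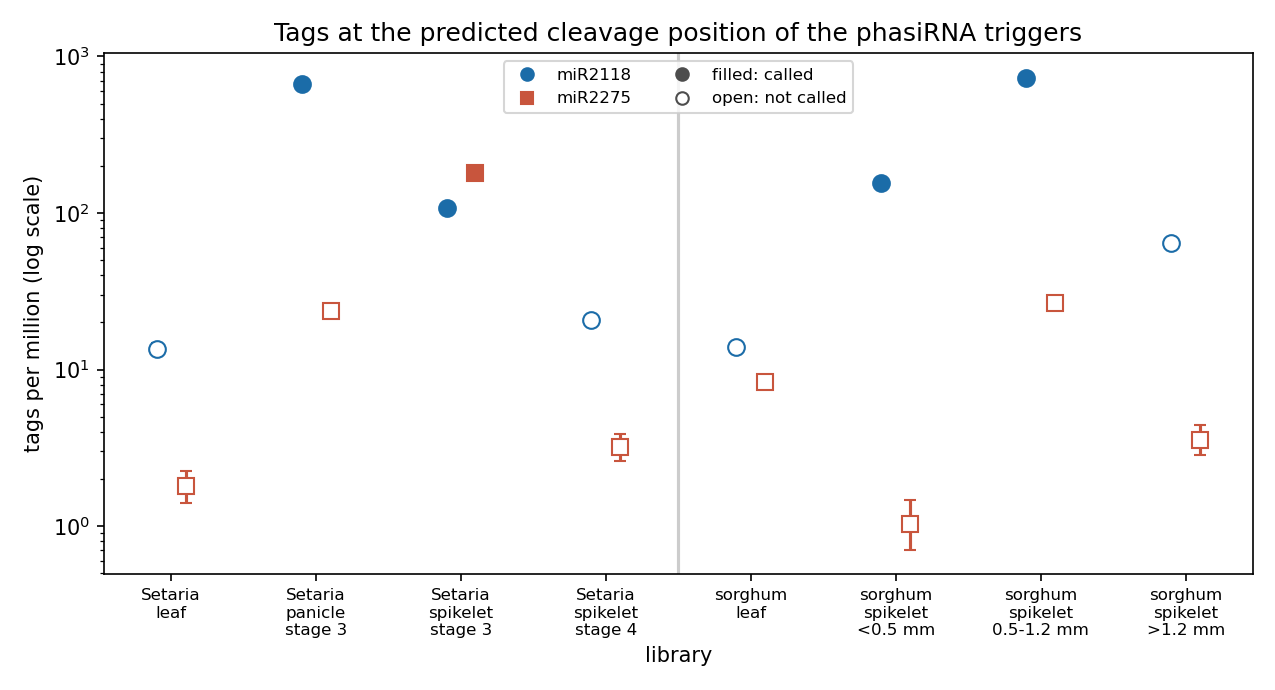
Tags per 1000000 counts (vertical log axis) at the predicted cutting position of miR2118 (circles) and miR2275 (squares) in the 8 libraries (horizontal axis), with 95% Poisson intervals and filled symbols for called families. miR2118 peaks at 670 TPM in the Setaria panicle and 731 TPM at 0.5 to 1.2 mm in sorghum, and miR2275 at 180 TPM in Setaria stage 3 spikelets.

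Other families also differed between the reproductive libraries of a species. In Setaria, miR156, miR160, miR408 and miR529 were highest in the panicle, by 1.73 (1.68 to 1.78), 1.75 (1.71 to 1.79), 3.14 (2.84 to 3.46) and 1.67 (1.52 to 1.84) or more against either spikelet library. Over their own background these smallest ratios came to 0.86 (0.81 to 0.91), 1.71 (1.66 to 1.76), 2.38 (2.09 to 2.71) and 0.98 (0.82 to 1.14). These intervals hold the background fixed and leave out its own error. The panicle's miR156 background included its leading miR529 tag. With the median of the offsets instead, the miR156 ratio to background was 64.6 in the panicle and 22.0 in stage 3 spikelets. miR164 was highest in stage 4 spikelets, by 2.84 (2.74 to 2.94) against the panicle and 3.38 (3.26 to 3.51) against stage 3 spikelets. miR319 was 1.22 (0.98 to 1.46) higher in stage 4 than in stage 3 spikelets. In sorghum, miR160 was 1.08 (1.05 to 1.10) higher at over 1.2 mm than at under 0.5 mm, and miR171 was 2.69 (2.25 to 3.18) lower on the log2 scale at over 1.2 mm. Over own background these differences came to 1.56 and 3.44. By TPM miR529 stood within 0.12 log2 units between any 2 of the sorghum spikelet libraries, but over its own background it was 0.66 (0.56 to 0.76) higher at under 0.5 mm and 0.44 (0.33 to 0.56) higher at 0.5 to 1.2 mm than at over 1.2 mm. tasiARF was 0.59 (0.33 to 0.86) higher at under 0.5 mm than at 0.5 to 1.2 mm.

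**Figure D3:**
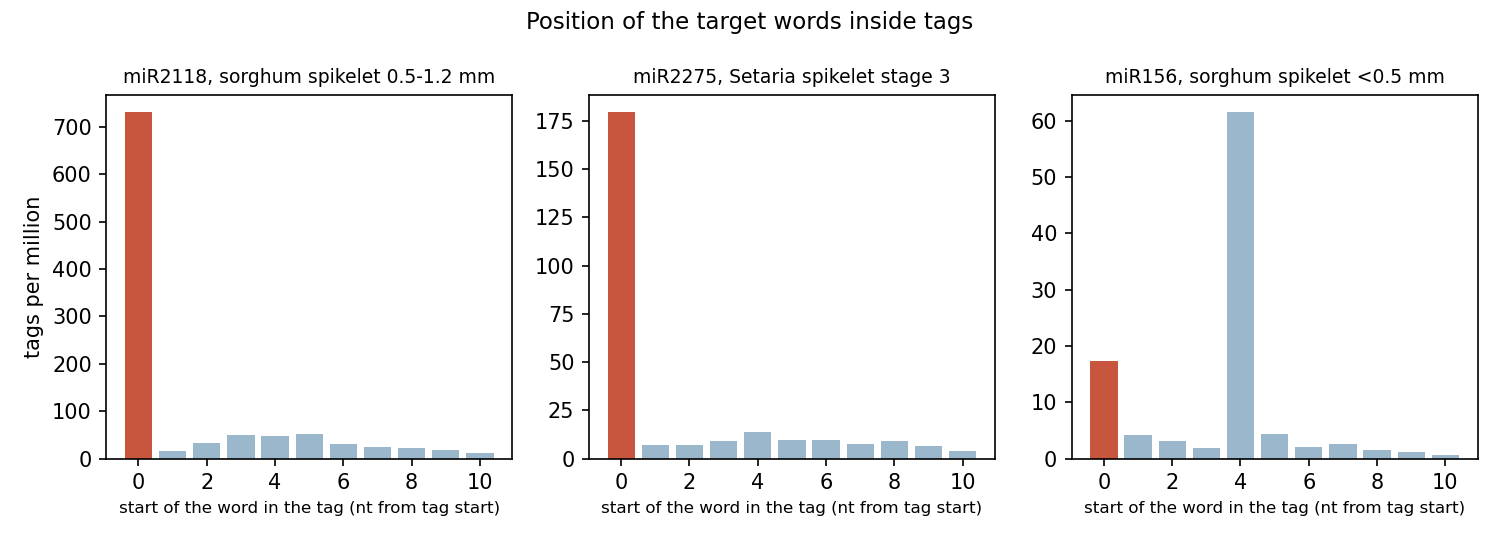
Tags per 1000000 counts (vertical axis) by the position at which a family's words start inside the tag (horizontal axis, nt from the tag start), for miR2118 and miR2275 in the libraries of their peaks and for miR156 in sorghum spikelets with anthers under 0.5 mm. The bar at 0 is the predicted cutting position, and the miR156 panel has its highest bar at 4, with 1844 counts against 520 at 0. The leading miR529 tag of that library holds the miR156 word at 4.

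The miR156 word in sorghum spikelets was most frequent 4 nt inside the tag, with 1844, 1244 and 1460 counts in order of anther length, against 520, 311 and 610 at the tag start. Those counts entered the miR156 background, and miR156 was not called in these libraries. With the median of the offsets as background, a choice made after the data were seen, miR156 was called at under 0.5 mm and over 1.2 mm and not at 0.5 to 1.2 mm. The miR171 word had a further peak 3 nt inside the tag in sorghum, with 356 counts in leaf against 503 at the start and 143 at over 1.2 mm against 45.

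Identical tags were compared between libraries to see how far libraries of 1 species resembled each other. After thinning, a median of 23.2% of the distinct tags of the smaller library were shared within a species (19.5% to 35.5% over 12 pairs) and 3.51% between species (2.22% to 4.81% over 16 pairs). The 3 sorghum spikelet libraries shared 31.8% to 35.5% with each other and 20.5% to 25.0% with sorghum leaf, a gap that coincides with the difference in unread bases. In Setaria, leaf shared 23.5% with the panicle and 19.5% and 19.8% with stage 3 and stage 4 spikelets, while the 3 reproductive libraries shared 22.2% to 23.4% with each other.

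Among words outside the listed families with the largest excess at the tag start, the ratio was largest in leaf for 8 of 10 Setaria words and 7 of 10 sorghum words. In Setaria the words ranked by this ratio were GTCAGGGAGG, TATCGAGTAG, TACCTGGTTG, GAACACTTGC, TCAAAAGAGG, ACACGATGGA, TACGTGGTTG, ATTTATTTCA, GTGCCATGCT and AATCGAAATT. TACGTGGTTG differs by 1 base from TACCTGGTTG, at 51.1 against 30654 TPM in Setaria leaf. Both are counted here, and whether the rarer is a misread form was not tested. GTCAGGGAGG reached 14044 TPM in Setaria leaf, 1577 TPM in the panicle and 114 and 236 TPM in stage 3 and stage 4 spikelets, and its tag GTCAGGGAGGTCGCCAGCAA made up 78.2% of it. GAACACTTGC reached 7483 TPM in Setaria leaf and 84.4 to 163 TPM in the reproductive libraries. GTGCCATGCT was the one Setaria word highest in the panicle, at 1034 TPM against 260 to 491 TPM in the other Setaria libraries. TATCGAGTAG ranked by its 692 TPM in stage 4 spikelets, and the same word stood at 87432 TPM in sorghum leaf, so that carry-over from that library is not excluded for it.

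In sorghum the words were TATCGAGTAG, TACCTGGTTG, TTCATGGACG, GCCGAACAAG, ACTCCAACTC, TTCCTCACAA, GTCTCTTCGG, GATTCAGTAT, AGACTCGACG and TATCGAGTAA. TATCGAGTAA likewise differs by 1 base from TATCGAGTAG, at 72.4 against 87432 TPM in sorghum leaf, and both are counted. TATCGAGTAG stood at 13.9 to 28.2 TPM in the sorghum spikelets, and GATTCAGTAT at 8112 TPM in leaf against 15.6 to 86.3 TPM in the spikelets. TTCCTCACAA reached 2563 TPM at over 1.2 mm against 5.57 TPM or less in each other library of either species, and TTCCTCACAACCGGCGCGAG made up 89.7% of it. GCCGAACAAG and GTCTCTTCGG stood at 35.4 and 48.0 TPM at under 0.5 mm, at 102 and 165 TPM at 0.5 to 1.2 mm and at 214 and 288 TPM at over 1.2 mm. Every word of both lists drew 72.8% to 98.2% of its counts from 1 tag.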

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

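The tests of explanations in this part were all chosen after the results they bear on had been seen, although the distinct-tag counts and the match with 1 mismatch that some of them use come from alternatives planned earlier, and although the criteria on distinct and separate tags replaced an earlier criterion on upstream pairing that was not met, and the AACCAAAT tags and the tags starting with 10 A bases were also chosen after their values were seen.

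miR2118 tags peaked in sorghum spikelets with anthers of 0.5 to 1.2 mm and in the Setaria stage 3 panicle. Chance matches of a 10-nt word are argued against by the distinct tags, which stood at 7.24 times background in the sorghum library and 9.61 times in the Setaria library, above all 10000 random lists, and by 157 and 230 tags differing by 3 or more bases at the predicted position, against at most 55 and 63 at any other offset. By the criterion first written, upstream bases pairing more often than reversed ones by their intervals, chance matches would have stayed possible, and the argument rests on the later criteria. A few abundant tags do not account for the peaks. Without the 10 most abundant separate tags of each library the smallest log2 ratio to the other stages was 2.53 (2.44 to 2.62) in sorghum and 3.25 (3.15 to 3.35) in Setaria. Totals do not account for the unscaled counts. These exceeded those of each other stage by 1.75 (1.71 to 1.8) or more in sorghum, whose peak library has the smallest total. In Setaria, where the totals differ 1.17-fold and 1.23-fold, they did so by 2.86 (2.81 to 2.91) or more. Set against the totals, these counts give the TPM ratios again, so they are no separate support for the peaks. Developmental stage, as the design names it, and differences in preparation between single libraries stay open and were not tested. So does organ in Setaria, where the panicle and the stage 3 spikelets carry the same stage number, on a scale that the labels do not define.

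miR2275 was called in Setaria stage 3 spikelets and in no sorghum library, a difference between species that was itself not tested. A sorghum site that differs from the listed words at 1 of tag positions 3 to 10 stays open. With 1 mismatch allowed, the highest percentile in the sorghum spikelets was 87.5. That setting kept 21 of the 40 calls and so can miss an excess, although it placed miR2275 in Setaria stage 3 spikelets at percentile 99.8. Whether the Setaria excess arose from chance matches at a few abundant tags stays open. Distinct tags stood at 2.63 times background, above all 10000 random lists, but 46 separate tags lay at the predicted position, against a mean of 46.0 and a highest value of 63 at the other offsets, so that the excess rests on the abundance of few sequences. Stage, organ and species stay open and were not tested.

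Tags with 2000 or more counts in 1 library and under 1% of that level elsewhere were found at 0.0337% to 0.708% of their source count in libraries with the same share of unread bases (median 0.115%, 18 pairs) and at 0% to 0.0622% in libraries with the other share (median 0.00481%, 17 pairs). Sorghum leaf gave 321 of these tags, Setaria leaf 33, Setaria stage 3 spikelets 14, sorghum over 1.2 mm 2 and the Setaria panicle 1, and a restriction to sources with at least 10 tags, used at first, had kept the 2 ranges apart. Carry-over of reads between libraries sequenced together stays open, since over all 5 sources the lowest share on the same side, 1 count (interval 0.000853% to 0.188%), lay below the highest on the other side (0.0435% to 0.0861%) with overlapping intervals. For the sorghum leaf tags, low levels of the same transcripts in the sorghum spikelets stay open too, and are consistent with shares of 0.0296% to 0.0406% there, against 0.000187% to 0.00421% for the tags of Setaria libraries in the same 3 libraries. Apart from that comparison no biological explanation was tested for this pattern, and the labels give no sequencing runs. Species and share of unread bases also partly coincided. For tags of Setaria libraries, every library with the other share was a sorghum spikelet library. The same-share libraries were the other Setaria libraries and sorghum leaf, where these tags stood at 0.0337% to 0.114%. For sorghum leaf tags it was the reverse, and every same-share library was from Setaria, at 0.103% to 0.397%.

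AACCAAAT at tag positions 4 to 11 pairs with miR2275 positions 1 to 7 and the next target base. Tags that held it there, whether or not they start with a listed word, reached 2836 TPM in Setaria stage 3 spikelets. This was 144 times their background, against 0.771 to 4.06 times in the other 7 libraries. In those spikelets 3 tags led by GTGAACCAAATGAGCTTATG made up 88.2% of them, and none of the 3 starts with a listed miR2275 word. Tags that start with 10 A bases, which no comparison used, made up 1.27% of the counts in Setaria leaf. The same kind of tag made up 0.864% in sorghum spikelets over 1.2 mm, against 0.0204% to 0.158% in the remaining 6 libraries.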

How the results depend on the processing

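Except for the median background, the alternatives here were planned, and the cause of each change below was not tested. No paired analysis was possible because each tissue or stage had 1 library. Comparisons by gene and around stop codons, and their alternatives, were not run because no genome was given. The calls of miR395 and sorghum leaf miR528 rest on 59 and 96 counts, and both were kept at a minimum of 30 counts and lost with background offsets from 3 and with the median background. Calls stayed within 1.5 times the reported number in 58 of 72 combinations of library and setting, and the shared-tag medians moved little without thinning (22.2% within and 3.74% between species) or with tags of at least 2 counts (27.6% and 3.03%). Of 80 alternative log2 ratios to leaf, 76 kept their sign, 38 of them outside the counting interval. A kept sign is less than a kept direction, which needs all 3 intervals to exclude 0. With distinct tags, 0 of 5 directions were kept in Setaria and 2 of 5 in sorghum.

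With up to 1 mismatch, the number of called families was 5 in Setaria leaf, 4 in the panicle, 4 in stage 3 and 3 in stage 4 spikelets, and in sorghum 2 in leaf, 3 at under 0.5 mm, 2 at 0.5 to 1.2 mm and 4 at over 1.2 mm. In Setaria, 1 family, miR2275, was then lower in all reproductive libraries than in leaf, where none was before. Ratios to leaf reversed to −3.51 for Setaria miR2275, −0.52 for Setaria tasiARF and −0.72 for sorghum tasiARF. The stage ratios were 1.83 for sorghum miR2118, 2.12 for Setaria miR2118 and 1.52 for Setaria miR2275, and that of sorghum miR2275 reversed to −0.46.

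With distinct tags, 4 families were called at over 1.2 mm instead of 2, of which 1 was shared, since miR529 was lost. In Setaria 0 families were higher than leaf and 2 lower, miR156 and miR160. In sorghum 1 was lower, miR171, while miR160 and miR528, lower before, lost their direction, as did tasiARF. The stage ratios were 1.33 and 1.72 for sorghum and Setaria miR2118, 1.16 for Setaria miR2275 and 0.96 for sorghum miR2275.

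Over own background, 2 Setaria families, miR156 and miR160, were lower than leaf, sorghum miR156 became lower, sorghum miR528 lost its direction, and the sorghum tasiARF ratio reversed to −0.64. The miR2118 stage ratios were 2.10 in sorghum and 2.42 in Setaria. With the median of the background offsets, the Setaria miR156 ratio to background was higher in the panicle (64.6) than in leaf (47.4).

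With a 9-nt word, 6 families were called at over 1.2 mm, Setaria miR2275 lost its direction against leaf, and the stage ratios were 2.10 and 2.39 for sorghum and Setaria miR2118, 2.20 for Setaria miR2275 and 2.39 for sorghum miR2275. Without the most abundant tag, 5 were called at over 1.2 mm, 1 Setaria family was lower than leaf, and the stage ratios were 2.77 for Setaria miR2118, 2.63 for Setaria miR2275 and 2.34 for sorghum miR2275. At the 95th percentile, 8 families were called in Setaria leaf, 13 in the panicle and 5 at over 1.2 mm. With the median of the background offsets, chosen after an overlapping site had been seen, miR156 was gained in sorghum at under 0.5 mm and over 1.2 mm and miR528 in the Setaria panicle, and miR395, miR529, miR528 and tasiARF were each lost in 1 library.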

Other observations

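The tags in the next paragraph were chosen after their values were seen, and the pairing test after it was chosen and changed after its result was seen.

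Each species had an abundant tag that differed by 1 base from an abundant tag of the other. TGCCATGCTGCCAACTCTGC stood at 576 to 2205 TPM in the 4 Setaria libraries, highest in the panicle, and at 1.25 to 4.16 TPM in sorghum. AGCCATGCTGCCAACTCTGC stood at 584 TPM in sorghum leaf and 931 to 1154 TPM in the sorghum spikelets, and at 2.48 to 5.003 TPM in Setaria. TGCAATAAAGAGCTCTAGGT was abundant in every sorghum library, at 2806 TPM in leaf and 1688 to 2166 TPM in the spikelets, and stood at 2.57 to 15.2 TPM in Setaria. TCGTTAATTATGTAAGCATT reached 643 TPM in Setaria stage 3 spikelets and 0.751 TPM or less in each other library. ATTATCTAAATATACATTAT reached 12040 TPM in Setaria leaf, 223 TPM in the panicle and 20.3 and 28.5 TPM in stage 3 and stage 4 spikelets.

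Bases upstream of miR2118 and miR2275 tags were read from overlapping tags of the same library to see whether they pair with small RNA positions 11 to 16 at 5 or 6 of these 6 positions. The test was written before it was run but after the peaks had been seen, with the criterion that the interval of the paired share lie wholly above that of the small RNA bases read backwards. It was first run with overlaps of 14 nt, widened to at least 12 nt and returned to 14 nt after these results had been seen. With 14 nt, 5 of 30 joined miR2118 tags in the Setaria panicle paired, against 0 read backwards, and in sorghum at 0.5 to 1.2 mm 1 of 17 paired, against 1. For miR2275 in Setaria stage 3 spikelets, 3 of 8 paired, against 0. With 12 nt, 16 of 99, 6 of 75 and 4 of 17 paired, against 7, 1 and 0, but tags with shuffled bases were joined 75, 55 and 18 times, for miR2275 more often than the real ones. The criterion was met in none of these cases at either overlap. For miR156, run for comparison, it was met in the Setaria panicle, where 9 of 15 tags paired with 14 nt (32.3% to 83.7%), against 0 (0% to 21.8%), although 8 tags were joined after shuffling. It was not met for miR156 in Setaria stage 3 spikelets, where 4 of 8 paired with 14 nt (15.7% to 84.3%), against 0 (0% to 36.9%), and 7 of 18 with 12 nt (17.3% to 64.3%), against 0 (0% to 18.5%). The joined tags at 14 nt held 91.7% and 81.7% of these miR156 counts. The criterion depends on the number of joined tags, however, and intervals from 8 tags are wide whatever share of counts they hold. For miR2118 and miR2275 the joined tags held 5.83%, 9.07% and 21.01% of the counts, and the test does not decide between a site and a chance match.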
